A study of Saccharomyces cerevisiae SK1 with 8 samples.

How the data were processed

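Polyadenylated RNA was sequenced from 8 cultures of diploid SK1 budding yeast, 2 biological replicates in each of 4 groups. Per the labels' protocols, cells were taken 3 h after dilution of an overnight culture into rich medium at 30 °C. At dilution they received anhydrotetracycline (aTC, the inducer) or its solvent DMSO. All strains carried a 3V5-tagged truncated Pus1 under a tet operator promoter at his3, and TetR and TetR-Tup1 at ura3. In the deletion strain the native PUS1 gene was replaced by KanMX.

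Per the labels, libraries were made with a directional kit and sequenced on a NovaSeq X. Reads were aligned with STAR, whose version is not given, per the submitters' processing notes. The deposited values are raw counts per gene made with featureCounts 2.0.1, per the file headers. Per the file headers, uniquely aligned reads were counted over exons and summed by transcript, with no strand option and no option for reads that touch more than 1 feature. A read in an overlap of genes is then dropped, and a read on the opposite strand is counted. Of the 6663 genes listed, 1464 (22%) overlap another listed gene, and their values are uncertain. Unique alignment also leaves near-identical copies uncertain, such as SSA1 and SSA2, HSP82 and HSC82, TDH2 and TDH3 and the paired ribosomal protein genes.

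The headers do not name the genome build, and coordinates are given as in the files. The files cover 16 chromosomes and no mitochondrial genome. Gene symbols came from the RefSeq table of the S288C assembly R64, which matched 5931 of the 6663 identifiers. The other 732 kept their systematic names. R64 was also used for the operator search described in the closing section.

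Total counts ran from 51331492 to 61960514 per library. At these depths 3 reads, the limit that a count of 0 allows, correspond to 0.0484 to 0.0584 CPM (counts scaled to a common library size). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. CPM values were scaled by the trimmed mean of M values (TMM, factors 0.963 to 1.05).

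Differences were tested in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood F test on all 8 libraries, with 1 mean per group and no block (4 residual degrees of freedom). The default expression filter kept 5932 genes and removed 731. Benjamini-Hochberg adjustment ran over the genes tested, and a gene was called at an adjusted p under 0.05. The common dispersion was 0.00296, a biological coefficient of variation of 5.44%. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. There were 7 comparisons: aTC against DMSO in the deletion and in wild type, deletion against wild type in DMSO and in aTC, the difference between the 2 responses (the interaction), and each factor averaged over the other. With TMM scaling, the largest median log2 fold change over all tested genes was 0.011 in size among the 7 comparisons.

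Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. The 32 lists, fixed before the data were examined, cover pseudouridine synthases, tRNA modification and processing, aminoacyl-tRNA synthetases and Gcn4-controlled amino acid synthesis. Other metabolic lists are methionine and sulfur assimilation, purine and one-carbon synthesis, glycolysis and fermentation, glucose-repressed carbon use, the TCA cycle with the retrograde response, the respiratory chain, ergosterol, and the iron, zinc and phosphate regulons. Stress lists are general stress, Hsf1 chaperones, the proteasome, oxidative stress, the unfolded protein response, drug resistance and cell wall integrity. The remaining lists are cytosolic ribosomal proteins, ribosome biogenesis, the mitochondrial ribosome, mitochondrially encoded genes, replication, histones, mitosis, haploid-specific genes, meiotic genes, construct and marker genes, and neighbours of the edited loci. All but the mitochondrially encoded genes, of which the files hold 0, had at least 5 tested members. The pseudouridine synthase and construct lists hold PUS1, the gene deleted or induced by design. Camera was not run on them without PUS1, so their calls do not stand for the other members. The symbol MLP1 in the cell wall list was matched to the gene of that standard name, YKR095W, although it is also an alias of KDX1.

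Named genes followed a rule fixed at the same time. In each pairwise comparison the rule took the 10 largest changes each way among called genes with a standard symbol whose libraries did not overlap between groups. For the averaged comparisons it took 5 each way. It added up to 4 called members of each list that was called or had at least 3 called members, and always PUS1, the other pseudouridine synthases, HIS3, URA3, TUP1, RNR2, NIP7 and LEA1. Where fewer than 10 genes passed, the 5 of smallest unadjusted p were added.

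The test was run on simulated counts for aTC against DMSO in the deletion, with 200 changed genes among 5916. It called 70% of genes changed 1.25-fold, 92% of those changed 1.5-fold, 100% at 2-fold and 98% at 4-fold. It made 192 calls, of which 12 were false. Counts were drawn for each gene on its own, with no deviation shared across a library. The shares called therefore need not hold for the real libraries. In a simulation on 5919 genes, a shift of the ribosome biogenesis list by -0.3 gave a median of -0.301, and 0 of the other lists were called by camera. That simulation does not measure false list calls in the real libraries, where the members of a list can deviate together.

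Alternatives were DESeq2-style size factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (a CPM of 5 in 2 libraries), a replicate block, fits of only the groups compared, counts thinned to the shallowest library, a camera prior count of 0.5, and each library left out in turn. Values without PUS1, and the cell wall list with KDX1 in place of MLP1, were added after seeing the data. The operator search and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Strand-specific and isoform-level expression were not analysed here, since the files hold gene counts without strand. With 2 libraries per group, an exact permutation test of a single value cannot give a p under 0.333. Each genotype is 1 strain, so other differences between the strains cannot be separated from the deletion.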

Results

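The study asks what a truncated isoform of the pseudouridine synthase Pus1 does in growing yeast, by switching it on in a wild-type strain and in a strain that lacks the native PUS1 gene. RNA was counted for 6663 genes in 8 libraries, 2 biological replicates each of the deletion with aTC, the deletion with DMSO, wild type with aTC and wild type with DMSO. Total counts were 54962651 and 54658278 for the deletion with aTC, 51331492 and 60057357 for the deletion with DMSO, 61960514 and 52994181 for wild type with aTC, and 51714455 and 57702051 for wild type with DMSO. Across genes, log2 CPM of replicates correlated at 0.997 (wild type with aTC) to 0.999 (deletion with DMSO). All group values have n = 2. Along the first principal component (34.7% of variance) the deletion with DMSO lay at 12 and 13 and the 6 other libraries at -6.41 to -0.615. Along the second (31.1%), the deletion with aTC lay at 8.38 and 12.2 and the deletion with DMSO at 1.04 and 1.75. Wild type with DMSO lay at -7.31 and -6.65, while the replicates of wild type with aTC lay apart, at -8.86 and -0.547. Both components include PUS1, the deleted and induced gene, whose CPM ran from 0.03823 to 1124 across libraries. Components without PUS1 were not computed, so the place of the deletion with DMSO may rest partly on PUS1 itself.

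PUS1 (YPL212C, chromosome 16, 149155 to 150789, minus strand, in the files' coordinates) encodes a synthase that makes pseudouridine in tRNAs and other RNAs, and its counts followed the labels in all 8 libraries. The deletion with DMSO had 2 and 4 reads in its libraries, a mean CPM of 0.0518 ± 0.0192 (SD). Wild type with DMSO had a CPM of 218.4 ± 3.67. With aTC the deletion reached 837.7 ± 94.7, which is 383% of the native level, and wild type reached 1101 ± 32.1, or 504%. The deletion had 16000 times more reads with aTC than with DMSO (95% counting interval 7360 to 43600), and wild type with DMSO had 3930 times more than the deletion with DMSO (1800 to 10700). In wild type the rise was 5.04-fold (log2 2.33, SE 0.0757, edgeR quasi-likelihood adjusted p = 2.9e-08). The counts join the native transcript and the construct, so they do not tell the isoforms apart. HIS3, which the strain labels name at the construct, had 0 or 1 read in each library, so no transcript with the HIS3 sequence of the reference was seen beyond that, and it was not tested.

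**Figure D1:**
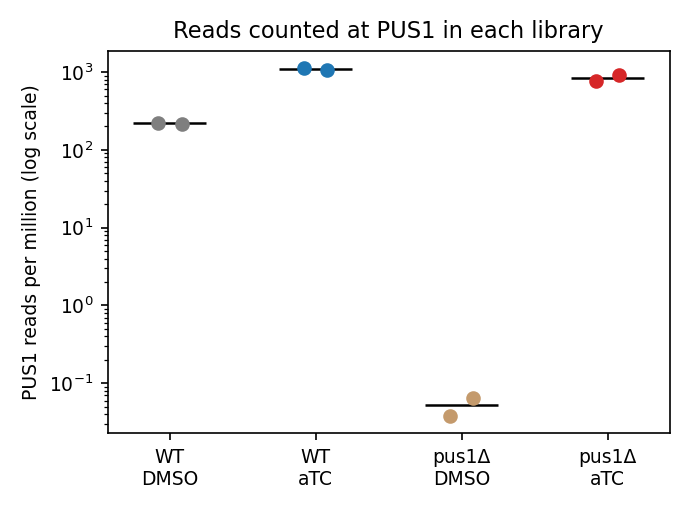
CPM of PUS1 in each library on a log axis, by group. Points are libraries and lines are means of 2, from 0.0518 in the deletion with DMSO to 1101 in wild type with aTC.

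In the deletion, aTC induced the isoform in cells without native PUS1. Among called genes with a standard symbol, the largest rises beside PUS1 were in ADE17, which encodes an enzyme of purine synthesis, at 3.19-fold (log2 1.67, SE 0.069), and in YEL1, a guanine nucleotide exchange factor gene, at 3.02-fold (log2 1.59, SE 0.0659). YJL027C, which has no standard symbol and lies beside RNR2, rose by a log2 of 1.64 (SE 0.155, edgeR adjusted p = 4.15e-04), between these, and was named after its value was seen. SKT5, a gene for chitin synthase activation, rose 2.47-fold (log2 1.30, SE 0.062), and MRX3, a mitochondrial protein gene, 2.11-fold (log2 1.08, SE 0.119). Genes of arginine synthesis fell together: ARG3 2.48-fold (log2 -1.31, SE 0.104), ARG5,6 1.66-fold (log2 -0.73, SE 0.0932), ARG1 1.59-fold (log2 -0.67, SE 0.118), CPA1 1.58-fold (log2 -0.66, SE 0.0697) and ARG8 1.48-fold (log2 -0.57, SE 0.0582). CAR2, which acts in arginine breakdown, rose 1.57-fold (log2 0.65, SE 0.0778). By edgeR quasi-likelihood the adjusted p was 1.36e-07 for ADE17 and YEL1, 4.65e-07 for SKT5, 0.00137 for MRX3, 8.53e-05 for ARG3, 9.07e-04 for CPA1 and 0.00242 for CAR2.

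Smaller rises in the deletion were in ECM21 (log2 0.54), an arrestin-related gene for removal of membrane transporters, YPC1 (0.50), a ceramidase gene, NNK1 (0.45), a kinase gene and BNA4 (0.44), of NAD synthesis. Smaller falls were in PXR1 (-0.62) and BUD20 (-0.47), genes of ribosome assembly, PHO84 (-0.52), the high-affinity phosphate transporter gene, and GFD2 (-0.38). The other pseudouridine synthase genes were not called, with log2 values from -0.17 (PUS9) to 0.20 (PUS6) and -0.12 for PUS7. TUP1 (0.31) and URA3 (0.42), present in the construct or beside it, and RNR2 (0.17) missed the threshold, at edgeR adjusted p = 0.0576, 0.0769 and 0.0993. NIP7 (0.00) and LEA1 (-0.03), which neighbour PUS1, also did not pass.

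In all, edgeR quasi-likelihood called 30 of 5932 genes in the deletion, 21 higher and 9 lower, 7 of them over 2-fold, and 1341 had an unadjusted p under 0.05. PUS1 is 1 of the 30. DESeq2 called 374 genes, 125 higher and 249 lower. A fit of only the deletion libraries called more genes than either, as given below with the other alternatives. The count was 13 without pus1Δ aTC replicate 1, 10 without pus1Δ DMSO replicate 1, 9 without pus1Δ DMSO replicate 2, 547 without WT aTC replicate 1 and 549 without WT aTC replicate 2. ADE17, YEL1, SKT5, MRX3, ARG3, CPA1 and ARG8 were called with each library left out. Of the other named genes, 9 lost the call without pus1Δ aTC replicate 1 (edgeR adjusted p up to 0.287), 8 without pus1Δ aTC replicate 2 (0.0748), 10 without pus1Δ DMSO replicate 1 (0.439) and 11 without pus1Δ DMSO replicate 2 (0.356). ARG5,6 and ARG1 were lost in all 4 cases, and CAR2 without pus1Δ aTC replicate 1 and pus1Δ DMSO replicate 2.

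Among the fixed lists, 6 were called by camera in the deletion. Ribosome biogenesis genes, which build ribosomes in the nucleolus, were lower (median log2 -0.17, 90 tested), with 0 members called by edgeR over all genes and 28 lower when adjusted over the list alone (41 lower at an unadjusted p under 0.05 and 20 by DESeq2). For ribosome biogenesis, camera gave an adjusted p = 5.81e-09, and an adjusted p = 0.974 with an estimated correlation. Mitochondrial ribosome genes were lower (median -0.09, 73 tested, 0 members called by edgeR either way, 23 lower at an unadjusted p under 0.05 and 7 by DESeq2). For the mitochondrial ribosome, camera gave an adjusted p = 1.67e-05, and an adjusted p = 0.974 with an estimated correlation. General stress genes were higher (median 0.08), with 0 of 40 called by edgeR over all genes and 6 higher adjusted over the list alone (12 higher at an unadjusted p under 0.05 and 4 by DESeq2). For general stress, camera gave an adjusted p = 0.0034, and an adjusted p = 0.904 with an estimated correlation. Ergosterol genes were higher (median 0.10), with 0 of 27 called by edgeR over all genes and 5 higher adjusted over the list alone (10 higher at an unadjusted p under 0.05 and 5 by DESeq2). For ergosterol, camera gave an adjusted p = 0.00528, and an adjusted p = 0.974 with an estimated correlation. Construct and marker genes were higher (median 0.17, 7 tested), with PUS1 called over all genes and 4 higher and 1 lower adjusted over the list alone. For the construct list, camera gave an adjusted p = 0.00542, and an adjusted p = 0.824 with an estimated correlation. PUS1, induced by design, is in that list, and camera was not run without it. Replication genes were higher (median 0.07, 34 tested, 0 called by edgeR either way, 5 higher at an unadjusted p under 0.05 and 1 by DESeq2). For replication, camera gave an adjusted p = 0.0309, and an adjusted p = 0.974 with an estimated correlation. The ergosterol call ended without pus1Δ aTC replicate 1 (camera adjusted p = 0.0995) and the replication call without pus1Δ DMSO replicate 1 (0.307) or pus1Δ aTC replicate 2 (0.396). Gcn4-controlled amino acid synthesis missed the threshold (camera adjusted p = 0.054), with 5 of 45 members lower over all genes and 9 adjusted over the list alone.

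In wild type, where the isoform was induced beside the native gene, many of the same genes stood out. ADE17 rose 3.27-fold (log2 1.71, SE 0.0689), YEL1 2.97-fold (log2 1.57, SE 0.0664), SKT5 2.79-fold (log2 1.48, SE 0.0622), MRX3 1.81-fold (log2 0.86, SE 0.12) and CAR2 1.59-fold (log2 0.67, SE 0.0777). The arginine synthesis genes fell: ARG3 3.07-fold (log2 -1.62, SE 0.104), ARG5,6 1.94-fold (log2 -0.95, SE 0.0935), ARG1 1.83-fold (log2 -0.88, SE 0.118), CPA1 1.69-fold (log2 -0.76, SE 0.0698) and ARG8 1.66-fold (log2 -0.73, SE 0.0583). By edgeR quasi-likelihood the adjusted p was 1.29e-07 for ADE17, YEL1 and SKT5, 0.00863 for MRX3, 9.49e-06 for ARG3, 0.00668 for ARG1 and 2.72e-04 for CPA1. TIR1, a cell wall mannoprotein gene, rose 1.58-fold (log2 0.66), URA3, of uracil synthesis and the marker of the repressor construct, rose by 0.58, and MRM1, a mitochondrial rRNA methyltransferase gene beside HIS3, 1.39-fold (log2 0.47). DED1, an RNA helicase gene of translation initiation that lies on the other side of HIS3, rose 1.36-fold (log2 0.45). MRH1, a membrane protein gene (log2 -0.43), and ZRT1, the high-affinity zinc transporter gene (log2 -0.35), fell.

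By edgeR quasi-likelihood, 22 genes were called in wild type, 15 higher and 7 lower, 6 of them over 2-fold, and 296 had an unadjusted p under 0.05. DESeq2 called 49, and a fit of only the wild-type libraries called 11. The count was 14 without pus1Δ DMSO replicate 1, pus1Δ DMSO replicate 2, WT DMSO replicate 1 or WT DMSO replicate 2. URA3 lost the call with each library left out, TIR1 with each but WT aTC replicate 2, and ZRT1 with each but pus1Δ aTC replicate 2. MRX3 lost it without WT DMSO replicate 1 or 2, ARG1 without WT DMSO replicate 2, MRH1 without WT aTC replicate 1 or WT DMSO replicate 1 or 2, and DED1 without pus1Δ DMSO replicate 1 or 2, WT aTC replicate 1 or WT DMSO replicate 2. The edgeR adjusted p of these lost calls ran from 0.0524 to 0.386. TUP1 (log2 0.25, edgeR adjusted p = 0.245) was not called.

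The list most clearly lower with aTC in wild type was Gcn4-controlled amino acid synthesis, at a median log2 of -0.14. Of its 45 genes, 5 were lower over all genes, all of arginine synthesis, and 13 were lower adjusted over the list alone. For this list, camera gave an adjusted p = 3.75e-22, and an adjusted p = 0.462 with an estimated correlation. Purine and one-carbon genes were lower at a median of -0.09 (18 tested), though ADE17 rose over all genes, with 1 higher and 3 lower adjusted over the list alone. For purine genes, camera gave an adjusted p = 6.48e-04, and an adjusted p = 0.462 with an estimated correlation. Glycolysis and fermentation genes were lower (median -0.05, 23 tested, 0 called by edgeR over all genes and 2 lower adjusted over the list alone, 6 lower at an unadjusted p under 0.05 and 1 by DESeq2). For glycolysis, camera gave an adjusted p = 5.34e-04, and an adjusted p = 0.493 with an estimated correlation. Proteasome genes were higher (median 0.05, 36 tested, 0 called by edgeR over all genes and 1 higher adjusted over the list alone, 2 higher at an unadjusted p under 0.05 and 1 by DESeq2). For the proteasome, camera gave an adjusted p = 8.78e-04, and an adjusted p = 0.543 with an estimated correlation. Hsf1 chaperone genes were higher (median 0.07, 25 tested, 0 called by edgeR either way or by DESeq2, 1 higher at an unadjusted p under 0.05). For Hsf1 genes, camera gave an adjusted p = 0.00235, and an adjusted p = 0.543 with an estimated correlation. Neighbours of the edited loci were higher (median 0.04, 10 tested), with DED1 and MRM1 called over all genes and 3 higher adjusted over the list alone. For the neighbours, camera gave an adjusted p = 0.0162, and an adjusted p = 0.462 with an estimated correlation. Construct and marker genes were called higher, with a mean of 0.41 but a median of -0.0018, with PUS1 and URA3 called over all genes and 3 higher adjusted over the list alone. For the construct list, camera gave an adjusted p = 0.044, and an adjusted p = 0.462 with an estimated correlation. PUS1, induced by design, is in that list, and camera was not run without it.

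The other 7 lists called by camera in wild type were methionine and sulfur assimilation (median log2 -0.05, adjusted p = 0.00501), drug resistance (-0.05, 0.00679), mitosis (-0.03, 0.0162), the zinc regulon (-0.06, 0.0162), cell wall integrity (-0.06, 0.0279), the iron regulon (-0.07, 0.0337) and, in the higher direction, the mitochondrial ribosome (0.04, 0.00818). With camera and an estimated correlation the adjusted p = 0.543 for methionine, drug resistance and mitosis, adjusted p = 0.614 for zinc, adjusted p = 0.462 for cell wall and adjusted p = 0.801 for iron and the mitochondrial ribosome. Of the 14 list calls in wild type, 10 ended without WT aTC replicate 1 (camera adjusted p up to 0.904), which left 7 lists called, 8 without WT DMSO replicate 1 (up to 0.65), 3 without WT aTC replicate 2 (up to 0.24), and 2 each without WT DMSO replicate 2, pus1Δ aTC replicate 1 and pus1Δ aTC replicate 2 (up to 0.123). The calls of Gcn4, purine and glycolysis genes held with each library left out. Without WT DMSO replicate 1 the direction of camera turned for the mitochondrial ribosome (median -0.0014) and the Aft1 iron regulon (median -0.0026).

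The responses in the 2 backgrounds, which share no library, overlapped in 17 called genes, 12 higher and 5 lower, where 0.0637 would be shared by chance if the calls were independent. The shared genes include PUS1, the 5 arginine genes, ADE17, YEL1, SKT5, MRX3, CAR2, NNK1, MRM1 (log2 0.36 in the deletion and 0.47 in wild type), CAN1, the arginine permease gene (0.39 and 0.37), YCP4 (0.40 and 0.35) and RML2 of the mitochondrial ribosome (0.40 and 0.38). The last is YJL027C (1.64 and 1.70), a gene without a standard name beside RNR2. CAN1, YCP4, RML2 and YJL027C lie outside the naming rule and were named after their values were seen. All 35 genes called in either background had the same sign in both. Across genes, which are not independent replicates, the log2 responses correlated at 0.401, at 0.365 without PUS1 and at 0.302 without the called genes. The correlation was 0.196 without WT aTC replicate 2, 0.300 without WT DMSO replicate 2 and 0.126 with no filter on low counts.

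**Figure D2:**
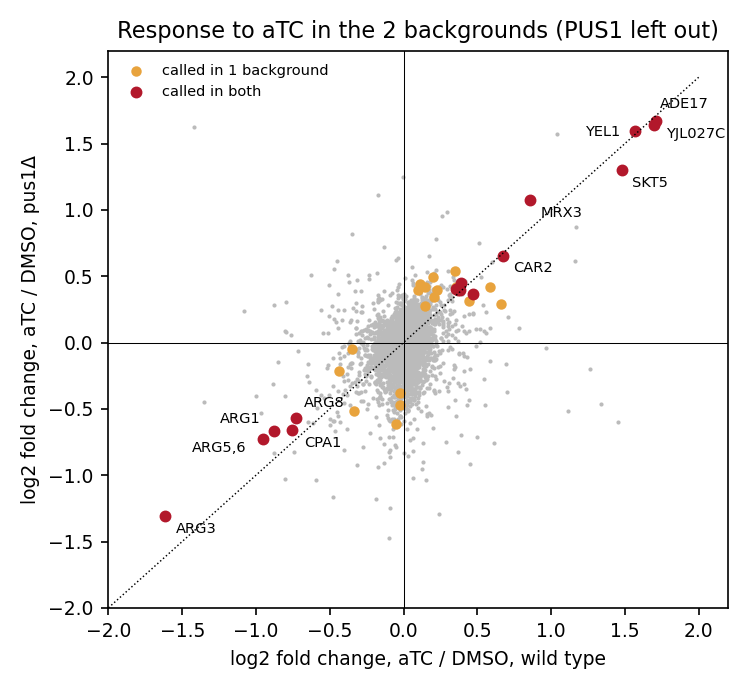
Log2 fold change with aTC against DMSO in wild type (x) and in the deletion (y) for each tested gene but PUS1. Red points were called in both backgrounds and orange points in 1, and the dotted line marks equal responses, with ARG3 at -1.62 and -1.31.

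Averaged over both genotypes, aTC changed 78 genes by edgeR quasi-likelihood, 46 higher and 32 lower, and 1121 had an unadjusted p under 0.05. ADE17 (log2 1.69, SE 0.0488), YEL1 (1.58), SKT5 (1.39) and MRX3 (0.97) rose and ARG3 (-1.46), ARG5,6 (-0.84), ARG1 (-0.77), CPA1 (-0.71) and ARG8 (-0.65) fell, and these 9 were called with each library left out. CAR2 rose by 0.66, ALD4 by 0.39, and RPN4, the transcription factor gene for the proteasome, by 0.44. CAT2, a carnitine acetyltransferase gene, rose by 0.30, SIP4, a regulator of gluconeogenesis, changed by -0.35, and CLB2, the mitotic cyclin gene, by -0.22. TUP1 (0.28, edgeR adjusted p = 0.0115) and URA3 (0.50, edgeR adjusted p = 0.00802) were called. The count was 20 and 24 without pus1Δ DMSO replicate 1 and 2, 32 without pus1Δ aTC replicate 1, 52 and 53 without WT DMSO replicate 1 and 2, and 551 without WT aTC replicate 1. TUP1, SIP4 and CLB2 each lost the call without pus1Δ DMSO replicate 1 or 2 or pus1Δ aTC replicate 1 (edgeR adjusted p up to 0.153), SIP4 also without WT DMSO replicate 2 and CLB2 without WT DMSO replicate 1, URA3 without pus1Δ DMSO replicate 1 or 2, RPN4 without pus1Δ DMSO replicate 1, and CAT2 without each but WT aTC replicate 1. DESeq2 called 220 genes.

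**Figure D3:**
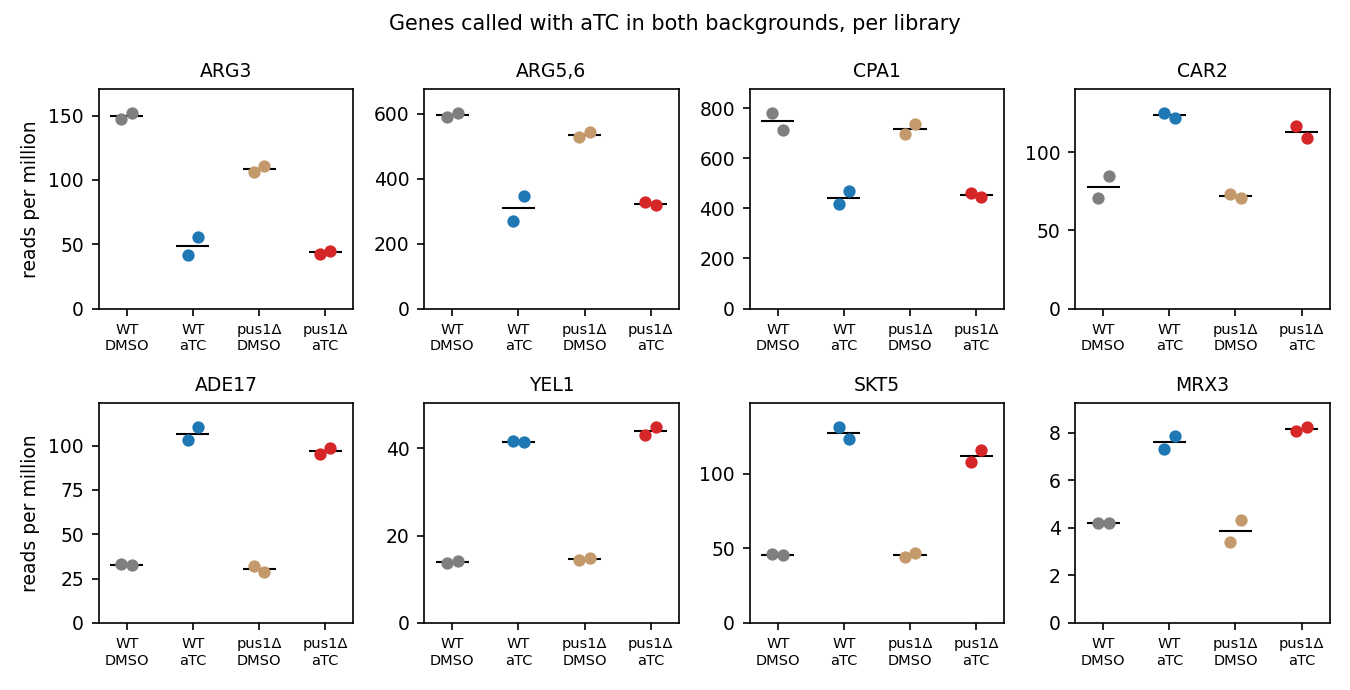
CPM per library of 4 genes of arginine metabolism (ARG3, ARG5,6, CPA1, CAR2) and of ADE17, YEL1, SKT5 and MRX3 in the 4 groups. Points are libraries and lines are means of 2, and for each gene the aTC libraries of a background do not overlap its DMSO libraries.

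Camera called 9 lists averaged over genotypes. Gcn4-controlled genes were lower at a median log2 of -0.09, with 8 of 45 called over all genes and 17 adjusted over the list alone. For Gcn4 genes, camera gave an adjusted p = 5.11e-08, and an adjusted p = 0.748 with an estimated correlation. Ribosome biogenesis genes were lower at -0.09, with 0 called by edgeR either way (27 lower at an unadjusted p under 0.05 and 5 by DESeq2). For ribosome biogenesis, camera gave an adjusted p = 1.48e-07, and an adjusted p = 0.782 with an estimated correlation. Mitosis genes were lower at -0.05. For mitosis, camera gave an adjusted p = 0.0194, and an adjusted p = 0.691 with an estimated correlation. Higher were general stress (median 0.06), ergosterol (0.06), replication (0.05) and construct genes (0.09), each at a camera adjusted p = 0.0139, the proteasome (0.05, 0.0145) and neighbours of the edited loci (0.04, 0.0443). With an estimated correlation by camera these 6 had an adjusted p = 0.691 (stress, construct, neighbours) or adjusted p = 0.782 (ergosterol, replication, proteasome). The construct list holds PUS1, induced by design. The calls of Gcn4, ribosome biogenesis and construct genes held with each library left out, and each other call ended without at least 1 of 7 libraries (camera adjusted p 0.0552 to 0.273). Without WT aTC replicate 2, 14 lists were called.

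Deletion against wild type in DMSO compares cells without and with native PUS1, with the construct uninduced. Heat shock genes were higher: HSP82, which encodes the inducible Hsp90 chaperone, 1.71-fold (log2 0.77, SE 0.127), HSP78, a mitochondrial disaggregase gene, 1.64-fold (log2 0.71, SE 0.0914), and SSA1, a cytosolic Hsp70 gene, 1.36-fold (log2 0.45, SE 0.0563). The near-identical copies HSC82 (log2 0.08) and SSA2 (0.14), looked up after the values of HSP82 and SSA1 were seen, were not called. YPS6, a yapsin protease gene (0.68), TPO4, a polyamine transporter gene (0.44), ALD4 (0.40) and MCR1, a mitochondrial cytochrome b5 reductase gene (0.39), were also higher. CHA1, the serine and threonine deaminase gene, was 1.79-fold lower (log2 -0.84, SE 0.0778), GPX2, a glutathione peroxidase gene, 1.51-fold (-0.59), HPF1, a cell wall glucosidase gene, 1.48-fold (-0.56) and ZRT1 1.46-fold (-0.55). By edgeR quasi-likelihood the adjusted p was 9.78e-04 for CHA1, 0.00334 for GPX2 and ZRT1, 0.00524 for HPF1, 0.00617 for SSA1, 0.00636 for HSP78 and 0.0384 for HSP82, YPS6, TPO4, ALD4 and MCR1.

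The 13 calls by edgeR quasi-likelihood in DMSO, PUS1 included, were 8 higher and 5 lower, and 980 genes had an unadjusted p under 0.05. DESeq2 called 116, DESeq2-style size factors gave 21 (12 higher and 9 lower), no filter 29 (20 higher and 9 lower), thinned counts 23 and a fit of only the DMSO libraries 261. Leaving out 1 library gave 29 (pus1Δ aTC replicate 1), 28 (pus1Δ aTC replicate 2), 2 (pus1Δ DMSO replicate 1), 1 (pus1Δ DMSO replicate 2), 106 (WT aTC replicate 1), 94 (WT aTC replicate 2), 4 (WT DMSO replicate 1) and 27 (WT DMSO replicate 2). CHA1 lost the call only without pus1Δ DMSO replicate 2, and GPX2 without either pus1Δ DMSO replicate. HSP82, HSP78, SSA1, MCR1, HPF1 and ZRT1 lost it without either pus1Δ DMSO replicate or WT DMSO replicate 1, and YPS6, TPO4 and ALD4 without each of the 4 DMSO libraries. The edgeR adjusted p of the lost calls reached 0.459 (pus1Δ DMSO replicate 1), 0.366 (pus1Δ DMSO replicate 2), 0.286 (WT DMSO replicate 1) and 0.0979 (WT DMSO replicate 2).

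Between genotypes in DMSO, camera with the preset correlation called 19 lists, and 0 with an estimated correlation. Of 90 ribosome biogenesis genes 87 had a negative log2 fold change (median -0.16), with 0 called by edgeR over all genes or adjusted over the list alone (25 lower at an unadjusted p under 0.05 and 1 by DESeq2). For ribosome biogenesis, camera gave an adjusted p = 2.7e-11, and an adjusted p = 0.517 with an estimated correlation. Cytosolic ribosomal protein genes were lower (median -0.09, 139 tested, 0 called by edgeR over all genes or adjusted over the list alone, 5 higher and 32 lower at an unadjusted p under 0.05, 1 higher and 4 lower by DESeq2). For ribosomal proteins, camera gave an adjusted p = 1.11e-07, and an adjusted p = 0.517 with an estimated correlation. Hsf1 chaperone genes were higher (median 0.27), with 3 of 25 called over all genes and 16 adjusted over the list alone. For Hsf1 genes, camera gave an adjusted p = 9.84e-09, and an adjusted p = 0.271 with an estimated correlation. General stress genes were higher (median 0.20), with 0 of 40 called by edgeR over all genes and 2 adjusted over the list alone (19 higher at an unadjusted p under 0.05 and 2 by DESeq2). For general stress, camera gave an adjusted p = 1.11e-07, and an adjusted p = 0.262 with an estimated correlation. Glucose-repressed genes were higher (median 0.18), with ALD4 called over all genes and 2 higher and 1 lower adjusted over the list alone. For glucose-repressed genes, camera gave an adjusted p = 2.29e-04, and an adjusted p = 0.262 with an estimated correlation. Gcn4-controlled genes were lower (median -0.13), with CHA1 called over all genes and 6 adjusted over the list alone. For Gcn4 genes, camera gave an adjusted p = 2.75e-08, and an adjusted p = 0.491 with an estimated correlation. Aminoacyl-tRNA synthetase genes were lower (median -0.11), with 0 of 19 called by edgeR over all genes and 4 adjusted over the list alone (9 lower at an unadjusted p under 0.05 and 1 by DESeq2). For the synthetases, camera gave an adjusted p = 1.27e-06, and an adjusted p = 0.473 with an estimated correlation. Glycolysis genes were lower (median -0.13), with 0 of 23 called by edgeR over all genes, 5 by DESeq2 and 1 higher and 8 lower at an unadjusted p under 0.05, and 1 higher and 6 lower adjusted over the list alone. For glycolysis, camera gave an adjusted p = 1.7e-05, and an adjusted p = 0.38 with an estimated correlation.

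Other lists called lower by camera in DMSO were purine (median log2 -0.13), tRNA modification (-0.05), mitosis (-0.09), ergosterol (-0.07), the proteasome (-0.06), construct and marker genes (-0.09) and the pseudouridine synthases (-0.07, of which PUS1 alone was called), at adjusted p from 4e-06 to 0.0069. The construct and pseudouridine synthase lists hold PUS1, the deleted gene, and camera was not run on them without it. Called higher were respiratory chain (median 0.10), mitochondrial ribosome (0.08), haploid-specific (0.14) and meiotic genes (0.09), at camera adjusted p from 2.26e-04 to 0.0162. For these 11 lists camera with an estimated correlation gave an adjusted p = 0.262 to an adjusted p = 0.638. Calls that ended were those of respiratory, mitochondrial ribosome, ergosterol and tRNA modification genes without WT DMSO replicate 1 (camera adjusted p up to 0.542), of ribosomal protein, haploid-specific and meiotic genes without WT DMSO replicate 2 (up to 0.27), of the mitochondrial ribosome without pus1Δ DMSO replicate 1 (0.264) and of meiotic genes without pus1Δ DMSO replicate 2 (0.265).

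With aTC, both strains hold the induced isoform and differ in the native gene, and PUS1 counts were slightly lower in the deletion (log2 -0.39, SE 0.0719, edgeR quasi-likelihood adjusted p = 0.0152). That call ended without pus1Δ aTC replicate 1 (-0.28) and without WT aTC replicate 1 (-0.37). Genes of ribosome assembly in the deletion were the lowest relative to wild type: RBP95 1.83-fold (log2 -0.87, SE 0.127), CGR1 1.81-fold (log2 -0.86), EBP2 1.80-fold (log2 -0.85), PXR1 1.79-fold (log2 -0.84), RRP14 and LOC1 1.78-fold (log2 -0.83), RRP15 (-0.82), NOP15 (-0.82), MPP6 (-0.79) and NOP53 (-0.75). Without WT aTC replicate 1 the differences were -0.49 for CGR1, -0.46 for EBP2 and NOP15, -0.50 for LOC1, -0.52 for RRP14, -0.54 for RRP15 and -0.40 for NOP53, and CGR1 and MPP6 lost the call. Higher were HXK1, a hexokinase gene that is repressed by glucose, 2.09-fold (log2 1.07, SE 0.168), DGR1 2.40-fold (log2 1.26), RRT6 1.79-fold (log2 0.84), HSP78 (0.77), SMA2, a sporulation gene (0.66), YPS6 (0.63), KNH1, a cell wall gene (0.62), and HES1, an oxysterol-binding protein gene (0.62). The edgeR quasi-likelihood adjusted p was 0.0135 for RBP95, 0.0161 for EBP2, 0.015 for HXK1, 0.0343 for DGR1 and 0.00662 for HSP78. DGR1 rests on 21 and 32 reads in the deletion with aTC and 11 in each wild-type library with aTC. DGR1 and HES1 were not called by DESeq2 or in a fit of only the aTC libraries, HES1 also not with thinned counts, and each kept the call in 3 of 8 fits with 1 library left out. They lost it without a pus1Δ library of either treatment or without WT aTC replicate 1 (edgeR adjusted p up to 0.264).

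In the list of ribosome biogenesis genes, 51 of 90 were lower over all genes and 1 was higher, NIP7 (0.23), which lies beside PUS1, while 66 were lower and 1 higher adjusted over the list alone (median log2 -0.30). For ribosome biogenesis, camera gave an adjusted p = 2.27e-18, and an adjusted p = 0.641 with an estimated correlation. The median level of the list, centred on the mean of the libraries, was -0.22 and -0.19 in the deletion with aTC, -0.02 and -0.03 in the deletion with DMSO, 0.22 and -0.03 in wild type with aTC, and 0.18 and 0.07 in wild type with DMSO, so the replicates of wild type with aTC stood apart. Without WT aTC replicate 1, the median difference was -0.17 and 12 members were called lower, and without pus1Δ aTC replicate 1 it was -0.28 with 0 called by edgeR quasi-likelihood and 65 lower at an unadjusted p under 0.05. Cytosolic ribosomal protein genes had 16 of 139 lower, RPL24B (-0.47), STM1 (-0.44) and RPL35B (-0.36) among them, and 3 higher, such as RPL22A (0.40), in counts that were equal over all genes and adjusted over the list alone (median -0.12). For ribosomal proteins, camera gave an adjusted p = 1.98e-08, and an adjusted p = 0.644 with an estimated correlation. Among tRNA modification genes 9 of 58 were lower by either adjustment, with the methyltransferase genes ABP140 (-0.54), TRM10 (-0.47) and TRM1 (-0.36) and the dihydrouridine synthase gene DUS3 (-0.36) (median -0.09). For tRNA modification, camera gave an adjusted p = 0.00102, and an adjusted p = 0.644 with an estimated correlation. Pseudouridine synthase genes had 3 of 10 lower over all genes, which are PUS1, CBF5 (-0.25) of the snoRNA-guided complex and PUS4 (-0.24), and 5 adjusted over the list alone (median -0.15). For the synthases, camera gave an adjusted p = 0.0222, and an adjusted p = 0.641 with an estimated correlation. PUS1, which differs by design, is in that list, and camera was not run without it. PUS7 (-0.22) was not called, at an edgeR adjusted p = 0.0505. Without WT aTC replicate 1 the calls of TRM10 (-0.27), TRM1 (-0.22), DUS3 (-0.225) and PUS4 (-0.15) ended, as did that of NIP7 (0.14) without pus1Δ aTC replicate 1.

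General stress genes were higher in the deletion with aTC (median log2 0.27), with 17 of 40 called over all genes and 25 adjusted over the list alone, including PNC1 (0.53), SOL4 (0.47), GSY1 (0.46) and SYM1 (0.44). For general stress, camera gave an adjusted p = 1.75e-09, and an adjusted p = 0.343 with an estimated correlation. Glucose-repressed genes were higher (median 0.22), with 8 of 30 called over all genes and 9 adjusted over the list alone, including HXK1, ALD4 (0.46), the glucokinase gene GLK1 (0.43) and the regulator CAT8 (0.42). For glucose-repressed genes, camera gave an adjusted p = 1.82e-04, and an adjusted p = 0.343 with an estimated correlation. Of the Hsf1 chaperone genes 7 were higher and 2 lower over all genes, such as HSP82 (0.56), SSA1 (0.47) and CNS1 (-0.49), and 11 higher and 2 lower adjusted over the list alone (median 0.17). For Hsf1 genes, camera gave an adjusted p = 0.00122, and an adjusted p = 0.641 with an estimated correlation. Haploid-specific genes had 3 of 23 higher by either adjustment, STE5 (0.43), BAR1 (0.39) and AXL1 (0.31) (median 0.23). For haploid-specific genes, camera gave an adjusted p = 5.54e-04, and an adjusted p = 0.641 with an estimated correlation. Meiotic genes had 4 of 48 higher over all genes and 2 adjusted over the list alone, with IME2 (0.52), SPO1 (0.34), HOP1 (0.30) and ZIP2 (0.28) (median 0.13). For meiotic genes, camera gave an adjusted p = 0.00237, and an adjusted p = 0.641 with an estimated correlation. The iron regulon had 3 of 28 higher by either adjustment, COT1 (0.38), ARN1 (0.28) and FRE5 (0.22) (median 0.16). For the iron regulon, camera gave an adjusted p = 0.00486, and an adjusted p = 0.644 with an estimated correlation. Mitosis genes had 5 of 23 lower over all genes and 8 adjusted over the list alone, with SIC1 (-0.36), BUD4 (-0.32) and CLB2 (-0.24) (median -0.10). For mitosis, camera gave an adjusted p = 0.0222, and an adjusted p = 0.641 with an estimated correlation. Without WT aTC replicate 1 the calls of CNS1 (-0.22), SOL4 (0.28), BUD4 (-0.20) and SIC1 (-0.21) ended, as did that of COT1 (0.25) without pus1Δ aTC replicate 1.

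Also lower with aTC were the mitochondrial ribosome (5 of 73 over all genes and 0 adjusted over the list alone, with MRPS17 at -0.35 and MRPL50 at -0.33), the proteasome (4 of 36 by either adjustment, with RPN5 at -0.30 and RPN11 at -0.27) and the aminoacyl-tRNA synthetases (SES1 at -0.22 over all genes and 0 adjusted over the list alone), with medians of -0.08, -0.10 and -0.05. For these 3 lists the camera adjusted p was 0.00486, 0.0063 and 0.0387, and with an estimated correlation they had an adjusted p = 0.754, adjusted p = 0.644 and adjusted p = 0.754. List calls that ended were those of aminoacyl-tRNA and pseudouridine synthase genes without WT aTC replicate 1 (camera adjusted p up to 0.22), Hsf1 genes without WT aTC replicate 2 (0.0539), mitosis, pseudouridine synthase and proteasome genes without pus1Δ aTC replicate 1 (up to 0.0885) and aminoacyl-tRNA genes without pus1Δ aTC replicate 2 (0.383). The calls of MRPS17 (-0.225), MRPL50 (-0.21) and SES1 (-0.13) ended without WT aTC replicate 1, and that of RPN11 (-0.16) without pus1Δ aTC replicate 1. HAC1, the transcription factor gene of the unfolded protein response, was lower (log2 -0.40), and so was GPX2 (-0.49).

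With aTC edgeR quasi-likelihood called 808 genes, 326 higher and 482 lower, 3 of them over 2-fold (HXK1, DGR1 and YIR021W-A at 1.35, the last named after its value was seen), and 1926 had an unadjusted p under 0.05. The count was 3 without pus1Δ aTC replicate 1, 63 without WT aTC replicate 1, 332 without pus1Δ DMSO replicate 1, 220 without pus1Δ DMSO replicate 2 and 1408 without WT aTC replicate 2. A fit of only the aTC libraries called 369, 90 higher and 279 lower. Of the genes that the naming rule selected, 80 lost the call without pus1Δ aTC replicate 1 (edgeR adjusted p up to 0.26), 66 without WT aTC replicate 1 (up to 0.304), 47 and 37 without pus1Δ DMSO replicate 2 and 1 (up to 0.0846), and 26 without pus1Δ aTC replicate 2 (up to 0.148). HSP78 and HAC1 were called with each library left out.

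The genotype difference was then compared between DMSO and aTC, which share no library, to ask whether it is smaller with the isoform induced. For the 13 genes called in DMSO, the log2 difference with aTC was a median of 0.822 of that in DMSO (quartiles 0.709 to 1.01), and all 13 had the same sign and were called with aTC. For the 808 genes called with aTC, the difference in DMSO was a median of 0.432 of that with aTC (0.281 to 0.605), and 780 had the same sign. Each ratio favours the condition its genes were chosen in. Without PUS1 the first was 0.840, and it was 0.0318 without pus1Δ DMSO replicate 2, when PUS1 alone is called, 0.413 without pus1Δ DMSO replicate 1 and 0.432 without WT DMSO replicate 2. The second was 0.791 without pus1Δ aTC replicate 1.

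Averaged over treatments, with 4 libraries per genotype, edgeR quasi-likelihood called 1260 genes, 593 higher and 667 lower in the deletion. HXK1 (log2 0.81), HSP78 (0.74), RRT6 (0.70), HSP82 (0.67), SSA1 (0.46), PNC1 (0.43), ALD4 (0.43), IME2 (0.42), TPO4 (0.40), MCR1 (0.39), the regulator gene ADR1 (0.39) and STE5 (0.37) were higher with each library left out. CHA1 (-0.76), RBP95 (-0.66), RRP15 (-0.58), RRP14 (-0.56), GPX2 (-0.54), the nucleolar prolyl isomerase genes FPR4 (-0.51) and FPR3 (-0.48), ABP140 (-0.43), ZRT1 (-0.40) and HAC1 (-0.30) were lower with each library left out. The edgeR quasi-likelihood adjusted p was 8.15e-05 for CHA1, 2.17e-04 for HSP78, SSA1 and GPX2 and 4.85e-04 for ABP140. Over 2-fold were PUS1 and YOR364W (1.16), named after its value was seen, and 2210 genes had an unadjusted p under 0.05. The count was 99 without pus1Δ DMSO replicate 2, 284 without pus1Δ DMSO replicate 1, 557 without pus1Δ aTC replicate 1, and 783, 781 and 750 without WT aTC replicate 1, WT DMSO replicate 1 and WT DMSO replicate 2.

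**Figure D4:**
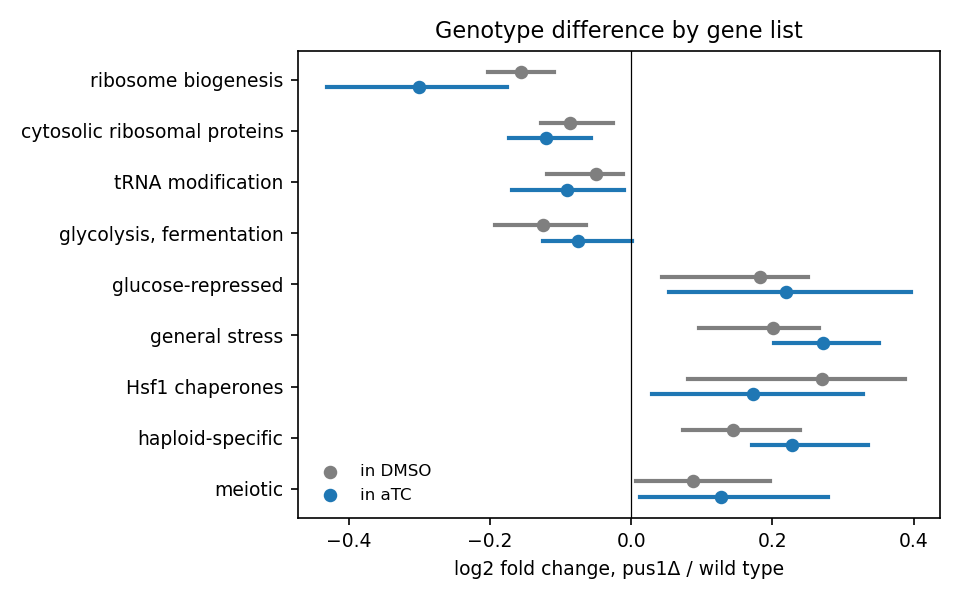
Log2 fold change of the deletion over wild type for 9 gene lists, in DMSO (grey) and aTC (blue). Dots are medians over the genes of a list and bars run between quartiles, and ribosome biogenesis lies lowest, at -0.16 and -0.30.

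Camera called 18 lists averaged over treatments. Ribosome biogenesis had 64 of 90 lower and 1 higher over all genes, and 75 lower and 1 higher adjusted over the list alone (median log2 -0.22). For ribosome biogenesis, camera gave an adjusted p = 2.12e-18, and an adjusted p = 0.468 with an estimated correlation. General stress had 24 of 40 higher over all genes and 28 adjusted over the list alone (median 0.23). For general stress, camera gave an adjusted p = 5.14e-10, and an adjusted p = 0.32 with an estimated correlation. Cytosolic ribosomal proteins had 35 of 139 lower and 4 higher over all genes, and 44 lower and 4 higher adjusted over the list alone (median -0.10). For ribosomal proteins, camera gave an adjusted p = 5.14e-10, and an adjusted p = 0.474 with an estimated correlation. Hsf1 chaperones had 13 of 25 higher and 2 lower over all genes, and 17 higher and 2 lower adjusted over the list alone (median 0.18). For Hsf1 genes, camera gave an adjusted p = 4.36e-06, and an adjusted p = 0.392 with an estimated correlation. Glucose-repressed genes had 12 of 30 higher and 1 lower over all genes, and 14 higher and 1 lower adjusted over the list alone (median 0.19). For glucose-repressed genes, camera gave an adjusted p = 7.42e-05, and an adjusted p = 0.32 with an estimated correlation. Respiratory chain genes had 8 of 39 higher and 1 lower by either adjustment (median 0.09). For the respiratory chain, camera gave an adjusted p = 0.0022, and an adjusted p = 0.778 with an estimated correlation. Glycolysis had 8 of 23 lower and 1 higher over all genes, and 9 lower and 1 higher adjusted over the list alone (median -0.08), with TDH2 at -0.26, ADH1 at -0.26 and ENO2 at -0.23. For glycolysis, camera gave an adjusted p = 0.00275, and an adjusted p = 0.468 with an estimated correlation. The phosphate regulon had 4 of 15 higher over all genes and 5 adjusted over the list alone, with PHO84 at 0.24 and PHO5 at 0.22 (median 0.15). For the phosphate regulon, camera gave an adjusted p = 0.0305, and an adjusted p = 0.392 with an estimated correlation.

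The other lists called by camera averaged over treatments were haploid-specific (median log2 0.17) and meiotic genes (0.12), higher, and aminoacyl-tRNA synthetase (-0.08), tRNA modification (-0.07), purine (-0.10), proteasome (-0.07), Gcn4 (-0.06), mitosis (-0.11), pseudouridine synthase (-0.10) and construct genes (-0.10), lower, at adjusted p from 1.48e-04 to 0.0244. With an estimated correlation by camera these had an adjusted p = 0.392 to an adjusted p = 0.778. The pseudouridine synthase and construct lists hold PUS1, the deleted gene, and camera was not run on them without it. The calls of Gcn4, construct and phosphate genes ended without WT aTC replicate 2 (camera adjusted p up to 0.181), that of the phosphate genes without WT DMSO replicate 2 (0.0634) and that of the respiratory chain without WT DMSO replicate 1 (0.12). Of the glycolysis and phosphate genes named here, TDH2 lost the call without pus1Δ DMSO replicate 2, ADH1 without pus1Δ DMSO replicate 1, and ENO2 without either of these, WT aTC replicate 1 or WT DMSO replicate 2. PHO84 lost it without pus1Δ DMSO replicate 1 or 2, pus1Δ aTC replicate 1 or WT DMSO replicate 2, and PHO5 without any of these or WT aTC replicate 1 (edgeR adjusted p up to 0.127 over these 5 genes). Lists called by camera in no comparison were histones (camera adjusted p = 0.414 here and 0.404 for aTC averaged over genotypes), the unfolded protein response (0.848 and 0.985), oxidative stress (0.821 and 0.985) and the TCA cycle with the retrograde response (0.335 and 0.373).

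The interaction tests whether the response to aTC itself differs between the backgrounds. PUS1 was the 1 gene called by edgeR quasi-likelihood, by DESeq2 and by limma-voom, and 429 genes had an unadjusted p under 0.05 by edgeR. The genes of smallest unadjusted p after PUS1 were IFH1, a regulator of ribosomal protein genes (log2 -0.42), YPL025C (-1.19), the splicing genes LSM3 (-0.51) and SLU7 (-0.51), and BUD20 (-0.44), all at an edgeR quasi-likelihood adjusted p = 0.66. The arginine genes ARG3 (0.31), ARG5,6 (0.22), ARG1 (0.21), ARG8 (0.16) and CPA1 (0.10) had unadjusted p from 0.0587 to 0.351 by edgeR. Without WT aTC replicate 2 the count of called genes was 175. Lists with a different response are given in the closing section.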

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

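The test of a single library behind the difference in ribosome biogenesis response was chosen after that result was seen. The values here stand out because a test of the difference between the 2 responses to aTC, deletion minus wild type, passed its threshold. Groups of 2 libraries are too small to test a single library against the rest of its group.

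PUS1 had a log2 difference of 11.56 by edgeR quasi-likelihood (adjusted p = 3.19e-11), a fitted value that depends on the prior count since the deletion with DMSO has 6 reads in all. Camera called 10 lists, each with an adjusted p = 0.769 with an estimated correlation and, apart from PUS1 in the construct list, with 0 genes called by edgeR, DESeq2 or limma-voom (at an unadjusted p under 0.05 by edgeR, 23 mitochondrial ribosome and 16 ribosome biogenesis genes were lower, of 429 genes in all). Median log2 differences were -0.157 for the mitochondrial ribosome (camera adjusted p = 6.04e-10), -0.158 for ribosome biogenesis (1.16e-06), 0.12 for Gcn4-controlled genes (6.9e-06), 0.113 for the iron regulon (0.00289), 0.091 for general stress (0.0156), 0.0649 for ergosterol (0.0222) and 0.0636 for construct and marker genes (0.0237). They were 0.065 for purine and one-carbon genes (0.025), 0.0707 for glycolysis (0.025) and 0.0912 for the zinc regulon (0.0402). The mitochondrial ribosome call held with each library left out. Calls ended for Gcn4, ribosome biogenesis, stress and ergosterol genes without WT aTC replicate 1 (camera adjusted p up to 0.213), for purine, iron, zinc and ergosterol genes without WT DMSO replicate 1 (up to 0.419), for stress and glycolysis without WT DMSO replicate 2 (up to 0.156) and for zinc and glycolysis without WT aTC replicate 2 (up to 0.205) or pus1Δ DMSO replicate 1 (up to 0.0625). They also ended for purine and zinc genes without pus1Δ DMSO replicate 2 (up to 0.0849), for purine, zinc, glycolysis and ergosterol genes without pus1Δ aTC replicate 1 (up to 0.401) and for construct genes without pus1Δ aTC replicate 2 (0.0631).

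Ribosome biogenesis genes were lower in the deletion than in wild type with aTC (median log2 -0.30, against -0.16 in DMSO). The median nearest 0 under DESeq2-style size factors or thinned counts was -0.3038. This does not decide on scaling or depth, since thinning keeps expected ratios and both ways of scaling take most genes as unchanged. The median stayed negative with each aTC library left out, and the value nearest 0 was -0.1675, without WT aTC replicate 1. This argues against a single library as the whole cause of the lower level without excluding it, since that fit leaves 1 wild-type library with aTC. For the difference between the responses, the median moved from -0.158 to -0.03352 without WT aTC replicate 1 and to -0.275 without WT aTC replicate 2, so WT aTC replicate 1 may account for most of it. A slower-growing or stressed state of the deletion cultures is a candidate explanation for the lower level. Ribosomal protein genes were also lower (median -0.1206) and general stress genes higher by camera, though with an estimated correlation camera called 0 lists in this comparison. Growth rates are not given in the sources used here. Loss of native Pus1 and other differences between the 2 strains stay open, and the design does not separate them.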

How the results depend on the processing

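The values without PUS1 and with KDX1 were chosen after the results were seen. Of 5390 named-gene values under the alternatives, 4563 were kept, 763 lost the call, 27 gained it, 37 moved and 0 called values reversed. A kept value is a call that kept its direction, or an uncalled value that stayed uncalled within its standard error. The direction of uncalled values was not followed. Some of the 19 alternatives were run on genes only or on lists only. Of 1260 list values 1010 were kept, 248 lost the call and 2 reversed by the direction of camera, without WT DMSO replicate 1 for aTC in wild type: the mitochondrial ribosome (median -0.001354) and the Aft1 iron regulon (median -0.002622), neither called there. With each library left out these medians ran from -0.001354 to 0.102 and from -0.1053 to -0.002622.

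Counts of called genes, given as main count and alternative, moved over 1.5 times as follows. DESeq2 gave 374 for 30 (aTC in the deletion), 49 for 22 (aTC in wild type), 116 for 13 (genotype in DMSO) and 220 for 78 (aTC averaged), and shared 30, 22, 13 and 77 genes with edgeR. For the 13 genes of genotype in DMSO, DESeq2-style size factors gave 21, no filter 29 and thinned counts 23, all with the 13 among them. Fits of only the groups compared gave 702 (aTC in the deletion), 11 (aTC in wild type), 261 (genotype in DMSO) and 369 (genotype in aTC), with 2 residual degrees of freedom. Across genes, deviations of samples with the same number correlated weakly (-0.156 to 0.143), which gives no sign of a pairing but cannot exclude one. The replicate block gave 28 for the 13 genes of genotype in DMSO and moved no other count of genes over 1.5 times. The correlation of the responses to aTC was 0.1263 without a filter. Camera with an estimated correlation called 0 lists in each of the 7 comparisons. Fry called 2 (aTC in the deletion), 1 (aTC in wild type), 8 (genotype in DMSO), 3 (genotype in aTC), 2 (interaction), 12 (genotype averaged) and 3 (aTC averaged), where camera called 6, 14, 19, 14, 10, 18 and 9. With KDX1 in place of MLP1 in the cell wall list, these counts by camera were equal, and the call in wild type stayed (median -0.06469, adjusted p = 0.0172). The cause was not tested.

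With 1 library left out, whose partner is assumed to vary like the other groups, counts of genes ran from 9 to 549 (aTC in the deletion), 14 to 27 (aTC in wild type), 1 to 106 (genotype in DMSO), 3 to 1408 (genotype in aTC), 1 to 175 (interaction), 99 to 1746 (genotype averaged) and 20 to 551 (aTC averaged). The lowest counts came without pus1Δ DMSO replicate 2 (aTC in the deletion, genotype in DMSO, genotype averaged), pus1Δ DMSO replicate 1 (aTC averaged) and pus1Δ aTC replicate 1 (genotype in aTC), and the highest without a WT aTC library. PUS1 ran from -0.5221 to -0.2833 for genotype in aTC, with the call lost at -0.2833 and at -0.3654 (without WT aTC replicate 1). Lists called ran from 7 to 18 for aTC in wild type and 6 to 14 for aTC averaged. The share of the genotype effect kept ran from 0.0318 to 0.8949, its reverse from 0.2992 to 0.7906 and the correlation of responses from 0.1955 to 0.4296. The cause was not tested. Depth limits genes near the floor.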

Other observations

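Of the tests here, those of a response to the truncated Pus1, of genes near the construct, of genes called in both backgrounds, of Gcn4 as the whole cause in the deletion, and of operator-like sites upstream of genes other than the first 4 were chosen after the results were seen.

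Averaged over treatments, single genes of other lists differed in the deletion, in both directions, while camera did not call the methionine, unfolded protein response, cell wall and replication lists as groups. Of 24 methionine and sulfur genes (camera adjusted p = 0.848) 3 were higher, such as SUL1 (log2 0.32) and MET3 (0.26), and SAM1 (-0.22) was lower. Of 20 unfolded protein response genes (0.848) 4 were higher, such as MPD1 (0.24) and KAR2 (0.22), and 3 lower, such as HAC1 (-0.30). Of 27 genes in the cell wall list (0.754) PST1 (0.27) was higher and 4 were lower, such as CCW12 (-0.23), TIR3 (-0.20) and MLP1 (-0.26). This MLP1 is YKR095W, a nuclear pore gene, since the symbol in the list is also an alias of KDX1, the cell wall integrity gene. With KDX1 (0.34, edgeR adjusted p = 0.00724) in its place, chosen after the values were seen, 2 were higher and 3 lower (camera adjusted p = 0.975). Of 34 replication genes (0.146) 5 were higher, such as RNR3 (0.28) and RNR1 (0.21), and the ribonucleotide reductase genes RNR4 (-0.19) and RNR2 (-0.17) were lower. RNR2 is also in the construct list, which holds PUS1 too. Camera called that list lower (0.0244), though not with an estimated correlation. CUR1 (0.57), a sorting factor gene for misfolded proteins, and PYK2 (0.33), the minor pyruvate kinase gene, were higher. By edgeR quasi-likelihood MPD1, HAC1 and PST1 were called with each library left out. SUL1, MET3, CUR1, PYK2, RNR4 and CCW12 lost the call without pus1Δ DMSO replicate 2, KAR2, SAM1, TIR3 and RNR2 without pus1Δ DMSO replicate 1 or 2, and MLP1 without either of these or pus1Δ aTC replicate 1 (adjusted p up to 0.0841). RNR1 lost it without pus1Δ DMSO replicate 2, pus1Δ aTC replicate 1, WT aTC replicate 1 or WT DMSO replicate 2, and RNR3 without these or pus1Δ DMSO replicate 1 (up to 0.109).

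Beside the construct, several genes had more reads with aTC. YOR203W, which overlaps the start of DED1, had 0 to 2 reads in the DMSO libraries and 10 to 21 in the aTC libraries. YJL027C, upstream of RNR2, whose promoter is part of the repressor construct, had a log2 difference of 1.67 averaged over genotypes, URA3 0.50, MRM1 0.42, DED1 0.38 and MCA1 0.20, all called by edgeR quasi-likelihood. These genes and the names of this group were chosen after their values were seen.

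ADE17, YEL1, SKT5 and MRX3 rose with aTC in both backgrounds. The difference between backgrounds was called by edgeR in none of the 4 (adjusted p from 0.66 to 0.94), and it was -0.18 for SKT5 (SE 0.0867, unadjusted p = 0.0664) and 0.22 for MRX3 (SE 0.17, unadjusted p = 0.223). Both strains carry TetR-Tup1, a repressor that aTC releases from DNA, and a candidate explanation is release from operator-like DNA: upstream of these genes (600 bases, R64 sequence of S288C, not SK1), the best sites had a mean of 5.67 mismatches to the 19-base tet operator, and the share of 100000 random draws as low was 0.00084 (median of draws 7.67). YEL1 and SKT5 share the site TATCTATAGATGATAGAGA (chromosome II, 107814 to 107832, 5 mismatches), and among other genes 4 of 78 with such a site were called higher against 35 of 5503 without (Fisher exact p = 0.002, 0.004 over 4 tests). One of the 4 is TUP1, whose counts hold the repressor construct, and without it 3 of 77 were called (unadjusted p = 0.0151). TUP1 and another of the 4, TIR1, lost the call without pus1Δ DMSO replicate 1 or 2 or pus1Δ aTC replicate 1, and TIR1 also without WT DMSO replicate 1 (adjusted p up to 0.145). The best sites of ADE17 and MRX3 had 6 mismatches each, and 9.94% of genes had as few. Of other genes called higher in both backgrounds, RML2 had 5 mismatches, CAN1 6 and NNK1 7. CAR2, YCP4 and MRM1 had 8, and 92.4% of genes had as few. Of genes with at most 4 mismatches, 0 of 9 were called by edgeR. A response to the truncated protein stays open, since no library has the inducer without the construct and the median difference between backgrounds over the 4 was -0.008057. For YJL027C, YOR203W, MRM1, DED1 and URA3, reads from the construct or control spreading from it also stay open. Of the other 16 genes within 5000 bases of HIS3, URA3 or RNR2, only MCA1 was called higher, against 39 of 5910 elsewhere (Fisher exact p = 0.1028), which does not decide it.

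The 5 arginine synthesis genes fell with aTC in both backgrounds (median log2 -0.67 in the deletion and -0.88 in wild type). The smallest median fall under other size factors or thinned counts, averaged over genotypes, was -0.7701. This does not decide on library depth or scaling, since thinning keeps expected ratios and both ways of scaling take most genes as unchanged. Lower Gcn4 activity as the whole cause in the deletion is argued against, since the lower quartile of the 37 Gcn4-controlled genes outside arginine synthesis was -0.09352 there, while in wild type 35 of these 37 were negative, so a part played by Gcn4 stays open (median -0.03742 averaged over genotypes). A candidate explanation is the arginine-responsive repressor complex, which represses ARG1, ARG3, ARG5,6 and ARG8 and turns on CAR1 and CAR2 when arginine is plentiful: CAR1, not looked up beforehand, was higher averaged over genotypes (log2 0.2795, edgeR quasi-likelihood adjusted p = 0.0344), but was called in neither background alone (0.29, adjusted p = 0.0863 in the deletion, and 0.27, adjusted p = 0.399 in wild type). Whether the inducer, the truncated Pus1 or TetR-Tup1 lies behind it cannot be read from 4 groups that all carry the construct.

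In fits of 4 libraries against 4, the genotype split called 655 genes by edgeR quasi-likelihood and the highest of the other splits 26. Only the genotype split itself, 1 of the 35, gave as many. That is the smallest share that 35 splits can give, and most other splits part the replicates of a group. The count therefore argues against chance for the genotype difference without excluding it. The treatment split called 26 genes, and 2 of the 35 splits gave as many, the other being the genotype split with 655, which points to a structure of the samples. This count alone does not decide on chance for the treatment difference. The 2 backgrounds share no library, and 17 genes, PUS1 among them, were called with the same sign in both. For independent calls 0.0637 would be expected (upper limit of the 95% range 1). The calls are not fully independent, since 1 fit of all 8 libraries gave both their spread for each gene. That spread does not set the sign of a change, and all 35 genes called in either background had the same sign in both. These values argue against chance for the shared genes as a set without excluding it.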
